A study of Mus musculus with 124 samples.

How the data were processed

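RNA was measured in cortex and liver of the same 62 mice. Per the labels' protocols, total RNA was taken with an miRNeasy kit, stranded libraries of polyadenylated RNA were made with a TruSeq kit and sequenced as single reads on a HiSeq 4000. The protocol text describes liver for every sample, and the cortex libraries are labelled as taken from an earlier study, so the preparation of the cortex is not given in the sources used here. Reads were trimmed with fastp, aligned with STAR 2.7.0e to mouse build GRCm38 (mm10) and normalised with edgeR, per the submitters' processing notes, which give no order or settings. The deposited values are log2 CPM, 1 table per tissue, as the sums of their antilogs per library show, and they were normalised separately by tissue. Neither read counts nor depth per library can be had from them, so the depth behind each value, and counting limits, are unknown, and low values carry more counting error than high ones. The tables hold 17185 entries in cortex (values −6.017 to 14.25) and 13373 in liver (−5.871 to 16.56). Entries without a gene name (77 in cortex with 0.0618% of the signal, 35 in liver with 0.0337%) were left out of the tests, which leaves 17108 and 13338 genes. In cortex 8 gene symbols stand on several entries. No column was without a sample, and how reads of overlapping or near-identical genes were assigned is not given in the sources used here.

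The values show that they had been adjusted before deposit. In cortex the difference between the label batches within groups was exactly 0 for every gene, so 1 dimension of the 62 had been removed. In liver 4 genes passed the threshold for the batch label (median absolute difference 0.084), but 2 dimensions had been removed, those of an unlabelled factor with 3 levels of 50, 4 and 8 libraries. In cortex the batch covariate of the fits accounts for the dimension removed. In liver the fits do not know of the factor, so their p-values are too small. With the factor as a covariate, the liver count 6 h after the end of deprivation (T36) went from 422 to 226. Replicate libraries differed by a root mean square of 0.23 to 0.376 (log2) over 97 pairs in cortex and of 0.329 to 0.601 over 97 pairs in liver, so none was a copy of another.

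The tests, covariates, gene lists, rule for named genes and alternatives were fixed before the data were examined, except that the 3-level factor of the liver and the gene set tests under other settings were added after seeing the data. Leaving out single libraries and same-batch controls were planned as alternatives, and their use to weigh the choroid plexus and clock patterns was chosen after the results were seen. Log2 values were tested as deposited, without a pseudocount or a filter, with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean trend). All 62 libraries of a tissue entered 1 fit of 17 groups with the label batch as an additive covariate (44 residual degrees of freedom), so that groups of 3 shared 1 estimate of the spread. Every deprived group lies in 1 batch, and the batch term rests on the controls. Deprived groups were set against undisturbed mice of the same ZT at 3 h and at 6 h, and F tests covered all times of a recovery day (2, 4, 2 and 2 df). The baseline F test (4 df) covered the 5 control times. The rhythm F test (2 df) covered the change of the cosine component (ZT0 minus ZT12) and the sine component (ZT6 minus ZT18) between controls and day 2. The tissues were compared at 6 h by an interaction in 1 fit of all libraries with 34 groups and batch within tissue (88 residual degrees of freedom). All tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a comparison, and the threshold was 0.05 with no limit on fold change. A fold change given beside group means includes the batch term.

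Gene lists with at least 5 measured members (34 in cortex, 32 in liver: pathways, cell type markers of both tissues and of their neighbours, ribosomal and respiratory genes) were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. The change of the core clock amplitude was tested by permuting the labels control and day 2 within each ZT, 100000 times, on the absolute median log2 ratio. Named genes were the 10 largest changes in each direction at 6 h, the 5 largest at 3 h and on each recovery day, the 10 largest baseline ranges, up to 5 rhythm changes and the 5 largest tissue differences in each direction. For changes after deprivation every deprived library had to lie above, or below, every control after the batch term. To these came up to 4 members of a list by smallest p and 26 genes always reported, of which 24 were measured in cortex and 25 in liver. Gene models without a name were counted and not named, and a few genes of this rule are not reported here. Genes of this rule whose call rested on single libraries are named in part and otherwise counted in the closing section. Gene positions came from the GENCODE annotation of GRCm38.

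Both tissues of a mouse share its code. The deviations of its libraries from their group means had a median correlation of 0.0299 (−0.088 to 0.161, 7 of 62 over 0.1), and with the animal as a block (correlation 0.0226) the tissue comparison called 1538 genes against 1483, all 1483 among them. The scripts were tested on simulated data of the same design, with noise drawn independently for each gene. On recovery days the change was put at the first time alone. Each simulation had 200 changed genes. Of those changed by 1 on the log2 scale, 91% were found in cortex at 6 h and 85.1% in liver at 6 h. The share found at 0.5 was 76.1% and 43.3%. False calls made up 6.35% of the genes called in cortex at 6 h and 8.59% in liver at 6 h. Over all comparisons this share ran from 2.29% (cortex day 2) to 8.59%. Alternatives were fits with no batch term, with the compared libraries only, with controls of the same batch only, with libraries centred on their median, without the lowest 20% of genes, with a robust fit, with a number block, with a cosine fit or batch 1 controls alone for the baseline, and without each library in turn. Figures were drawn with matplotlib 3.10.9. Whether the mice of a group were littermates or handled together is not given in the sources used here.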

Results

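Gene expression was measured by RNA sequencing in the cerebral cortex and the liver of the same 62 mice, with 1 library per mouse and tissue. The mice were 11 to 12 weeks old, fed freely and kept in 12 h of light and 12 h of darkness. Of these, 26 mice slept undisturbed and were killed at zeitgeber time (ZT, hours after light onset) 0 (n = 8), 3 (n = 3), 6 (n = 5), 12 (n = 5) or 18 (n = 5). The other 36 mice were kept awake by gentle handling for 6 h from light onset of the next day, which ran from T24 to T30 in hours from the start of the baseline day. They were killed in groups of 3 during deprivation (T27), at its end (T30) and during recovery at T36, T42, T48, T54, T60, T66, T72, T78, T192 and T198. The labels split the libraries of each tissue into batch 1 (40) and batch 2 (22). The deprived mice of T60, T66, T192 and T198 were all in batch 2, and those of the other times were all in batch 1. The values were log2 CPM (read counts scaled to the library total) for 17108 named genes in cortex and 13338 in liver. Each library summed to between 979200 and 1020000 CPM in cortex and to between 919700 and 1070000 CPM in liver, and the number of reads per library is unknown. Each deprived group was compared with the undisturbed mice of the same time of day, so that differences due to the hour itself were removed. Libraries are named by the code of the animal. Genes named for the size of their change at T27 or later had every deprived library above, or every one below, all control libraries of that time of day. Unless stated otherwise, a change is a log2 fold change ± its standard error (SE) from limma, with an adjusted p, and group levels are means ± SD in log2 CPM. With no gene changed, chance alone would give about 855 cortex genes and 667 liver genes an unadjusted p under 0.05. Gene positions are on mouse build GRCm38, and the genes given with one are protein coding unless stated.

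The undisturbed mice were first compared across the times of day. In cortex, the clock repressor gene Ciart had a log2 range of 2.11, and Dbp, an output transcription factor of the clock (chromosome 7, 45705088 to 45710203), was 3.05-fold higher at ZT12 than at ZT0 (adjusted p = 4.01e-19). Arntl, which encodes the clock activator BMAL1 (chromosome 7, 113207465 to 113314126), ran the other way and was 1.77-fold higher at ZT0 than at ZT12 (adjusted p = 4.01e-19). Per2, a clock repressor, was highest at ZT18 and lowest at ZT3, with a log2 range of 1.62. Among genes induced by neuronal activity, Arc was 6.07-fold higher at ZT0 than at ZT6 (adjusted p = 0.000591), Egr2 had a log2 range of 2.14, and Homer1, a scaffold protein of synapses, had a range of 1.09 with its highest mean at ZT18. Cirbp, which encodes a cold-inducible RNA-binding protein, was highest at ZT6 and lowest at ZT18 (log2 range 0.77). Other large ranges were those of Ano2, a chloride channel (2.57), Mc4r, a melanocortin receptor (2.36), Fmo2 (2.25), Rtp1 (2.22), Plin4, a lipid droplet protein (2.18), and Hif3a (2.11). Ttr, a thyroid hormone carrier made by the choroid plexus, had the largest range in cortex (3.43, highest at ZT3, adjusted p = 0.0011), which was no longer called without the ZT3 library T3N2 (adjusted p = 0.0941) or in a cosine fit (0.835). Pomc had a range of 2.51 (adjusted p = 0.0168), which was no longer called without T3N3 (adjusted p = 0.505). In all, 7162 of 17108 genes (41.9%) changed with the time of day in cortex (limma F test), of which 289 spanned over 2-fold, and 2083 of the 7162 had their highest mean at ZT18. With batch 1 controls alone, 4672 genes were called.

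In the liver of the same undisturbed mice several clock genes were among those with the largest swings. Npas2, a partner of the clock activators (chromosome 1, 39193731 to 39363236), was 164-fold higher at ZT0 than at ZT12 (adjusted p = 6.56e-25). Dbp was 121-fold higher at ZT6 than at ZT0, Nr1d1, a repressor of Arntl, 74-fold higher at ZT6 than at ZT18, and Ciart spanned 83.7-fold. The lowest means were −3.81 ± 0.91 for Npas2, −0.56 ± 0.81 for Dbp and −1.41 ± 0.77 for Ciart. The sizes of their folds thus rest on low values whose counts are unknown. Arntl spanned 17.2-fold and Per3 22.4-fold, and Per1 and Bhlhe41 had log2 ranges of 4.28 and 4.19. Further large ranges were those of Rgs16, a regulator of G protein signalling (67-fold), Usp2, a deubiquitinase (44.1-fold), Fam107a (log2 range 4.71), Lpin1, a phosphatidate phosphatase that was highest at ZT12 (4.68), and Elovl3, a fatty acid elongase that was highest at ZT0 (4.65). Of the metabolic genes, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 3.92-fold higher at ZT12 than at ZT6, Pck1, an enzyme of gluconeogenesis, had a range of 2.09, and Fasn, fatty acid synthase, 1.22. In all, 6937 of 13338 genes (52%) changed with the time of day, and 1283 of them spanned over 2-fold. The share of genes was not tested between the tissues, whose tables were normalised separately. The liver count was 4346 with batch 1 controls alone.

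The animals killed at T27 answered what 3 h of enforced wakefulness did in cortex. Activity-induced genes were among the largest rises: Egr2, a transcription factor (chromosome 10, 67535475 to 67542188), was 7.29-fold higher in the deprived mice (−0.30 ± 0.48, n = 3) than in the ZT3 controls (−3.17 ± 0.42, n = 3), a change of 2.87 ± 0.80 (adjusted p = 0.00922). Fosb rose by 2.06 ± 0.24 (adjusted p = 2.02e-08), Sik1, a kinase, by 1.95 ± 0.35, Dusp4, a phosphatase, by 1.67, Homer1 by 1.15 and Bdnf, a neuronal growth factor, by 1.12. Of 25 measured immediate early genes, 19 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 1.15 (camera adjusted p = 2.24e-17, and adjusted p = 0.113 with an estimated correlation). Per2 (chromosome 1, 91415982 to 91459324) was 2.8-fold higher, at 6.26 ± 0.17 against 4.77 ± 0.26 (n = 3 each, limma adjusted p = 2.02e-08), and the clock genes Cry1, Bhlhe40 and Nfil3 rose by 0.50, 0.99 and 0.64. Across the core clock list 5 of 20 rose and 2 fell (6 and 2 adjusted over the list alone). Cdkn1a, a cell cycle inhibitor, rose by 1.51 and Serinc2 by 2.05 ± 0.27. Of the always-reported genes, 14 of 24 passed the threshold and the other 10 lay between −0.28 and 0.17.

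Chaperone genes rose in the same cortex samples. In the endoplasmic reticulum list 16 of 20 rose and 0 fell by limma (16 adjusted over the list alone, median 0.41, camera adjusted p = 2.4e-17, and adjusted p = 0.0972 with an estimated correlation), among them Hspa5, the main chaperone of that compartment (0.83), Sdf2l1 (1.17), Creld2 (0.83) and Manf (0.60). Of 21 cytosolic heat shock genes, 10 rose (13 adjusted over the list alone, median 0.17, camera adjusted p = 8.53e-09, and adjusted p = 0.113 with an estimated correlation), such as Hsph1 (0.42), Dnajb1 (0.42) and Hspa8 (0.31). Of 19 glucocorticoid-responsive genes, 9 rose (10 adjusted over the list alone, median 0.31, camera adjusted p = 3.27e-05, and adjusted p = 0.221 with an estimated correlation), among them Tsc22d3 (0.64), Errfi1 (0.32) and Zbtb16 (0.43). Cirbp fell, by 0.58 on the log2 scale (adjusted p = 6.46e-06). Larger falls were those of Cep55, a protein of cell division (chromosome 19, 38055011 to 38074423), at −2.17 ± 0.47 (adjusted p = 0.000807), and Gpr151, an orphan receptor, at −1.53 ± 0.33. Choroid plexus markers were lower than in the ZT3 controls: 4 of 5 passed the threshold (5 adjusted over the list alone, median −1.27, camera adjusted p = 0.00029, and adjusted p = 0.113 with an estimated correlation), with Ttr (chromosome 18, 20665280 to 20674321) 10.2-fold lower, at 0.87 ± 0.46 against 4.22 ± 2.40 in the controls (not called without T3N2, adjusted p = 0.0915). The mean value of the 5 markers was −0.11, −0.10 and 0.20 in the deprived libraries, within the range of the 23 controls of the other times (−0.48 to 1.00), and 3.04, 1.35 and 0.79 in the ZT3 controls. Of 10 markers of meninges and fibroblasts, 3 fell (6 adjusted over the list alone, median −0.39, camera adjusted p = 0.00289, and adjusted p = 0.813 with an estimated correlation).

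In all, 2810 cortex genes changed at 3 h (limma), 1469 higher and 1341 lower, and 171 of them by over 2-fold. After centring of the libraries the balance turned, to 1324 higher and 1470 lower. Several named genes lost their call when single libraries were left out. Arc (2.11 ± 0.74, adjusted p = 0.0421) had an adjusted p of 0.134 without T3N2, 0.165 without T3N4, 0.0771 without T27S2, 0.106 without T27S3 and 0.0867 without T27S5. Fos (1.83 ± 0.60, adjusted p = 0.0285) had 0.0947 without T3N2, 0.128 without T3N4, 0.105 without T27S3 and 0.0653 without T27S5. The calls of Ttr (adjusted p = 0.00245 with all libraries) and Clic6 (−2.10 ± 0.49, adjusted p = 0.00178) were lost without T3N2 (0.0915 and 0.0504), and that of En2 (−1.76 ± 0.46, adjusted p = 0.00521) without T3N2 (0.0855) or T27S3 (0.0585).

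At the end of the 6 h of deprivation, activity-induced genes were higher in cortex. Arc, a regulator of synaptic strength (chromosome 15, 74669083 to 74672570), was 9.72-fold higher, at 9.08 ± 0.19 (n = 3) against 5.80 ± 1.01 (n = 5) in the ZT6 controls (3.28 ± 0.68, limma adjusted p = 0.000172), and Fos (chromosome 12, 85473890 to 85477273) was 6.62-fold higher (adjusted p = 0.000125). Of 25 immediate early genes, 24 rose (24 adjusted over the list alone) with a median of 1.43 (camera adjusted p = 2.05e-17, and adjusted p = 0.084 with an estimated correlation), including Egr2 (2.88), Nr4a1 (1.88), Junb (1.86), Fosl2 (1.31), Bdnf (1.28) and Homer1 (1.22). Heat shock genes rose in 14 of 21 cases (16 adjusted over the list alone, median 0.28, camera adjusted p = 7e-11, and adjusted p = 0.084 with an estimated correlation), with Hspb1 at 1.44 and Hsph1 at 0.60. Hspa1b rose by 0.93, although its reads are nearly those of its copy Hspa1a and the split between them is uncertain. Endoplasmic reticulum chaperones rose in 17 of 20 cases (17 adjusted over the list alone, median 0.48, camera adjusted p = 3.06e-15, and adjusted p = 0.084 with an estimated correlation), with Hspa5 at 1.08 (adjusted p = 2.53e-09), Manf at 0.78 and Calr at 0.70. Of 19 glucocorticoid-responsive genes, 15 rose (15 adjusted over the list alone, median 0.45, camera adjusted p = 2.05e-06, and adjusted p = 0.156 with an estimated correlation), among them Fkbp5, a co-chaperone of the glucocorticoid receptor (0.54).

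Cholesterol synthesis genes fell in cortex at 6 h: 17 of 23 were lower and 0 higher by limma (18 lower adjusted over the list alone, median −0.31, camera adjusted p = 6.89e-07, and adjusted p = 0.344 with an estimated correlation). They included Insig1, which holds back the sterol sensor (−0.74, adjusted p = 1.21e-07; chromosome 5, 28071363 to 28078662), and the enzymes Lss (−0.51) and Sqle (−0.46). Of the 20 core clock genes, 7 rose, among them Per1 (1.06), Per2 (1.02), Nfil3 (0.97), Npas2 (0.39), Arntl (0.25) and Clock (0.23), and 8 fell, among them Dbp (−0.93, adjusted p = 4.91e-08), Ciart (−0.66), Bhlhe41 (−0.54) and Tef (−0.26). Adjusted over the list alone these counts were 8 and 9, and the median of the list was −0.08 while its mean was 0.05. Cirbp (chromosome 10, 80165985 to 80172786) was 2.05-fold lower, at 5.14 ± 0.11 against 6.18 ± 0.08 (adjusted p = 3.44e-13), and Rbm3, its close relative, fell by 0.38. The largest falls were those of Adh1, an alcohol dehydrogenase (chromosome 3, 138260991 to 138290698; −2.35 ± 0.37, adjusted p = 2.1e-06), and Ntf3, a neurotrophin (chromosome 6, 126101412 to 126166910; −1.85 ± 0.33), followed by Cfap52 (−1.67), Lrrc29 (−1.65), Bace2, a protease (−1.59), Pla2g4e (−1.58), Abra (−1.57), Cldn22 (−1.56), Hes3 (−1.52) and Cdhr3 (−1.50). Rises outside the lists were led by Plekhg4 (chromosome 8, 105373274 to 105382862; 2.18 ± 0.19, adjusted p = 4.28e-12), Tnfrsf25, a receptor of the tumour necrosis factor family (2.09), Slco1b2, an organic anion transporter (chromosome 6, 141629518 to 141686646; 2.05 ± 0.45), Serinc2 (1.94) and Sik1 (1.91).

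Of 24 genes of the glutamatergic postsynapse, 9 rose and 4 fell in cortex at 6 h (10 and 5 adjusted over the list alone, camera adjusted p = 0.523), with Shank2, a scaffold protein, at 0.47 and Grm2, a glutamate receptor, at −0.53. Among the cell type markers, 1 of 12 microglial genes rose and 5 fell (1 and 5 adjusted over the list alone), and 3 of 12 oligodendrocyte genes fell (4 adjusted over the list alone, median −0.10). Ribosomal protein genes passed in 4 of 78 cases, 2 in each direction. In all, 5550 of 17108 genes changed (limma), 2678 higher and 2872 lower (2553 and 2503 without the lowest 20% of genes), and 282 of them by over 2-fold. Of the always-reported genes, 20 of 24 passed, and the other 4 lay between −0.18 and 0.20 with a lowest adjusted p of 0.0542. The falls of Nr1d1 (−0.32, adjusted p = 0.0236) and Per3 (−0.20, adjusted p = 0.0361) depended on single libraries. Nr1d1 had an adjusted p of 0.0741 without T30S1, 0.0587 without T30S3 and 0.0502 without T30S4. Per3 had 0.0558 without J76N1, 0.0822 without T6N3, 0.0515 without T6N4, 0.0509 without T30S1, 0.119 without T30S3 and 0.0894 without T30S4.

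The first recovery day (T36 and T42) was compared with the ZT12 and ZT18 controls. In cortex at T36, 6 h after the end of deprivation, Car12, a carbonic anhydrase (chromosome 9, 66713686 to 66766845), was 4.03-fold higher, at 4.04 ± 0.31 (n = 3) against 2.03 ± 0.07 (n = 5; limma F test adjusted p = 2.68e-14). Slco1b2 (2.30 ± 0.45), Timp1, an inhibitor of matrix proteases (2.01 ± 0.37), Fndc9 (1.70) and Slc23a3 (1.56) were also higher, and Ano2 (−1.92 ± 0.44), Rpe65, a retinoid isomerase (−1.40), and Scn10a, a sodium channel (−1.34), were lower. Some activity-induced genes were still raised, with 7 of 25 higher and 0 lower by limma (8 higher adjusted over the list alone, median 0.30, camera adjusted p = 0.000965, and adjusted p = 0.868 with an estimated correlation), led by Nptx2, a secreted synaptic protein (chromosome 5, 144545902 to 144557478; 1.44 ± 0.13), Bdnf (1.19), Egr3 (1.04) and Fosl2 (0.81). Core clock genes were lower in 7 of 20 cases and higher in 3 (8 and 3 adjusted over the list alone, median −0.28, camera adjusted p = 0.0032, and adjusted p = 0.699 with an estimated correlation). Ciart (−0.86), Bhlhe41 (−0.59) and Tef (−0.41) were lower, while Nfil3 (0.86) and Arntl (0.35, adjusted p = 9.68e-05) were higher. Rbm3 was at −0.75 ± 0.09 (adjusted p = 4.06e-08) and Cirbp at −0.39. Cdkn1a was still higher (adjusted p = 1.02e-06).

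Chaperone genes were higher in cortex at T36, and some were lower at T42. At T36, 10 of 21 heat shock genes were higher and 1 lower (14 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 3.27e-10, and adjusted p = 0.223 with an estimated correlation), such as Hsph1 (0.63), Hspa8 (0.45) and Stip1 (0.44), and 8 of 20 endoplasmic reticulum chaperones were higher (10 adjusted over the list alone, camera adjusted p = 0.000156, and adjusted p = 0.72 with an estimated correlation), such as Calr (0.55) and Hsp90b1 (0.46). At T42, 3 heat shock genes were lower and 0 higher by limma (7 lower adjusted over the list alone, median −0.09, camera adjusted p = 1.39e-06, and adjusted p = 0.644 with an estimated correlation): Hspa1b (−0.74), Hspa1a (−0.42) and Dnajb1 (−0.25). Of 12 oligodendrocyte markers, 1 was lower at T36 (5 adjusted over the list alone, median −0.25, camera adjusted p = 0.000965, and adjusted p = 0.793 with an estimated correlation). Counted over both times, 1983 genes changed (limma F test with 2 df), 2136 at T36 alone (1181 higher) and 177 at T42 alone (110 higher). Without T36S1 the day count was 1176 and the T36 count 1078, and the calls of Dbp (−0.64 at T36; adjusted p = 0.0764 without it), Nr1d2 (−0.33; 0.15), Per3 (−0.32; 0.252) and Homer1 (0.55; 0.0527, and 0.0639 without T36S2) were lost. The T42 count was 74 without T18N2, 77 without T42S2 and 52 without T42S6, and Dio3, a deiodinase (−1.58 ± 0.43 at T42, adjusted p = 0.0208), lost its call without each of them (0.0684, 0.0987 and 0.0951).

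The second recovery day (T48 to T66) had few changes in cortex, and those called one by one lay at T48. At T48, which was light onset of the next day, Ndst4, an enzyme of heparan sulfate synthesis (chromosome 3, 125404076 to 125728899), was 4.06-fold higher than in the ZT0 controls (2.65 ± 0.12, n = 3, against 0.63 ± 0.30, n = 8; limma F test adjusted p = 1.94e-05), and Gpr101, an orphan receptor (chromosome X, 57496668 to 57503757), was 4.28-fold higher (0.51 ± 0.98 against −1.59 ± 0.26, adjusted p = 0.00678). Slc23a3 (chromosome 1, 75125541 to 75133890) was 3.29-fold lower (−1.72 ± 0.24, adjusted p = 1.42e-05), Slc4a11, a membrane transporter, was at −0.89 and Etnk2, an ethanolamine kinase (chromosome 1, 133363572 to 133380336), at −0.70. Of the clock genes, Arntl was lower (5.53 ± 0.06 against 5.92 ± 0.05, −0.39 ± 0.06, adjusted p = 0.000899) and Dbp higher (0.76 ± 0.12, adjusted p = 0.00338). Over the core clock list 6 of 20 were higher and 1 lower (7 and 3 adjusted over the list alone, median 0.12, camera adjusted p = 0.0145, and adjusted p = 0.876 with an estimated correlation). Of 12 oligodendrocyte markers, 1 was higher (6 adjusted over the list alone, median 0.25, camera adjusted p = 2.65e-06, and adjusted p = 0.876 with an estimated correlation). Of the always-reported genes, 3 of 24 passed over the day, and Nr1d2 (0.38, adjusted p = 0.0219) did not without T48S1 (0.129), T48S4 (0.0931) or T0N2 (0.0513).

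In all, 132 cortex genes changed on the second recovery day (limma F test with 4 df), and 255 at T48 alone, 132 higher and 123 lower. The T48 balance turned after centring (105 higher and 143 lower) and without T48S3 (57 and 64). The day count was 321 without a batch term, 76 with a spread estimated from the compared libraries alone and 27 with controls of the same batch alone, and without a batch term T48 had 419 genes, T54 2 and T66 14. At T54, T60 and T66 limma called 0 genes, with 1750, 1198 and 1627 at an unadjusted p under 0.05, where chance gives about 855. These counts depended on single libraries. The day count was 68 without T48S3, 70 without T48S4, 79 without T0N5, 202 without T6N3, 230 without T66S2 and 947 without T54S4. At T48 the count was 157 without T48S1, 121 without T48S3, 139 without T48S4, 113 without T0N2 and 139 without T0N5. At T54 it was 806 without T54S4, 8 without T6N3 and 3 without J76N1. At T60 it was 2 without T60S2, and at T66 it was 25 without T66S2 and 4 without T18N2.

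Whether deprivation altered the daily rhythm itself was tested from the 4 times of the second recovery day against the same 4 times of the undisturbed mice. In cortex, core clock genes swung less on that day: 17 of 20 had a smaller amplitude, and the median ratio of the day 2 amplitude to the undisturbed one was 0.477 (permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). The ratio was 0.514 for Dbp, 0.48 for Nr1d1, 0.472 for Ciart, 0.593 for Per2 and 0.446 for Tef. The amplitude of Arntl went from 0.42 ± 0.02 to 0.15 ± 0.04 (log2, ± SE; ratio 0.351). Adjusted over the list alone, 11 of the 20 changed their rhythm by limma, all 11 with a smaller amplitude. In liver the median ratio was 0.973 (13 of 19 smaller, permutation p = 0.668), with ratios of 1.05 for Arntl, 0.973 for Dbp, 0.967 for Nr1d1 and 0.758 for Per2. Undisturbed amplitudes were larger in liver for every shared clock gene, such as 3.71 for Dbp against 0.81 in cortex. A loss of the same absolute size would therefore move a liver ratio less, and absolute losses were not tested between the tissues. The difference between the tissues over the 19 shared genes was −1.02 in the log2 ratio (permutation p = 1e-05, again the smallest possible). Over all cortex genes, limma called 2 genes (F test with 2 df), Arntl (adjusted p = 0.0158) and Sdk1, a neuronal adhesion protein (chromosome 5, 141241490 to 142215586; ratio 1.17, adjusted p = 0.0193). Over all liver genes it called 0, with 1241 at an unadjusted p under 0.05 and 1 called without T66S5, without T0N5, without a batch term or in a robust fit. The cortex count was 189 without a batch term and 0 (limma) with controls of the same batch alone. It was 0 without T12N6 or T60S4, 1 without T48S1, T60S3 or T0N3, 4 without J76N2 and 5 without T60S2. Further counts were 6 without T18N2 or T0N1, 8 without T48S4, 15 without T18N8, 29 without T48S3, 53 without T6N3, 90 without T66S2 and 1172 without T54S4. Arntl had an adjusted p of 0.072 without T12N6, 0.0718 without T48S1 and 0.0826 without T60S4. Sdk1 had 0.072 without T12N6, 0.112 without T60S3, 0.0826 without T60S4 and 0.0661 without T0N3. The median clock ratio in cortex stayed between 0.455 and 0.52 whichever library was left out.

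**Figure D1:**
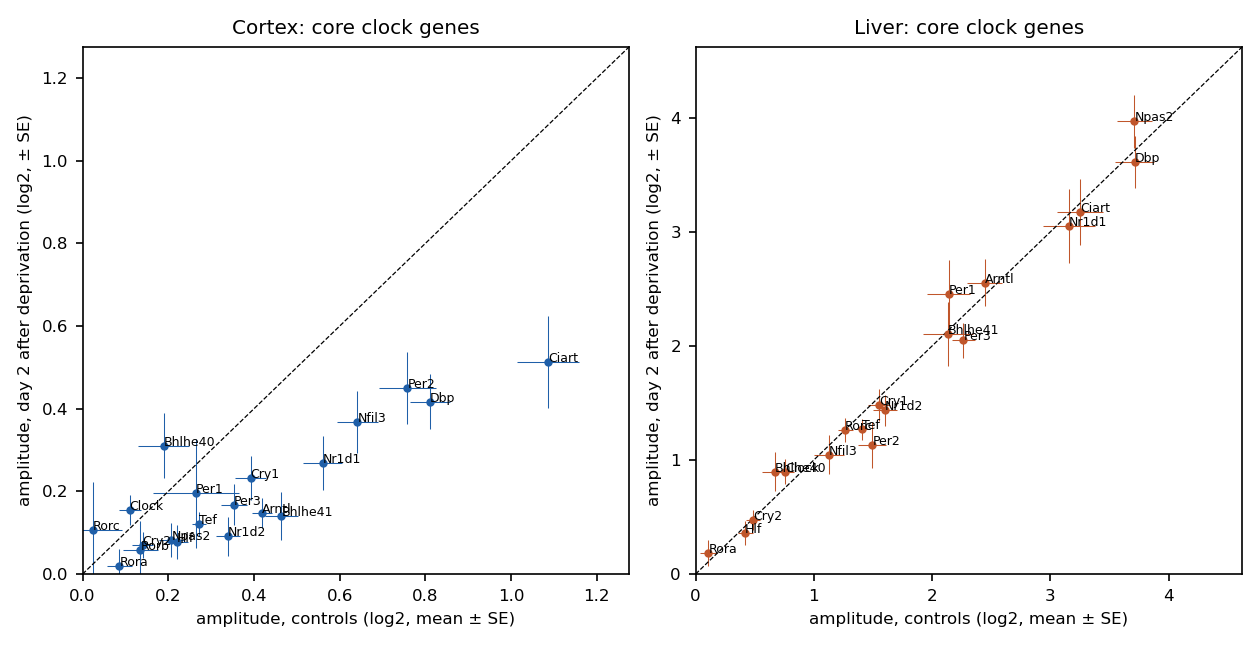
Amplitude of each core clock gene (log2, ± SE) in undisturbed mice on the x axis and on the second recovery day on the y axis, in cortex and in liver. In cortex 17 of 20 genes lie below the line of equal amplitude, with a median ratio of 0.477, and in liver the median ratio is 0.973.

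On the third recovery day (T72 and T78) and the eighth (T192 and T198) no cortex gene passed the threshold. On day 3 limma called 0 genes, with 1019 at an unadjusted p under 0.05 and 1 called without T6N3, 5 without a batch term and 2 with a spread estimated from the compared libraries alone, and on day 8 it called 0, with 1459 at an unadjusted p under 0.05 and 20 called without J76S2. Homer1, Arc, Per2, Dbp and the other always-reported genes (24 measured) lay between −0.40 and 0.70 on day 3 (lowest adjusted p 0.174) and between −0.26 and 0.71 on day 8 (lowest adjusted p 0.594). Taken one at a time, T72, T78, T192 and T198 also had 0 called genes (limma), with 1067, 902, 1081 and 1489 at an unadjusted p under 0.05. Without a batch term the T72 count was 6, without T72S4 it was 3, without T0N8 or T0N9 it was 1, and the T198 count was 76 without J76S2, 2 without J76S3 and 1 without J76N1. In simulated data of the same design, noise was independent for each gene and the change was put at T72 or T192 alone. On day 3, 67.2% of genes changed by 0.5 on the log2 scale and 88.1% of those changed by 1 were found. On day 8 these shares were 74.6% and 88.1%. Deviations shared across genes were not simulated, so the shares may be too high for the real libraries.

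**Figure D2:**
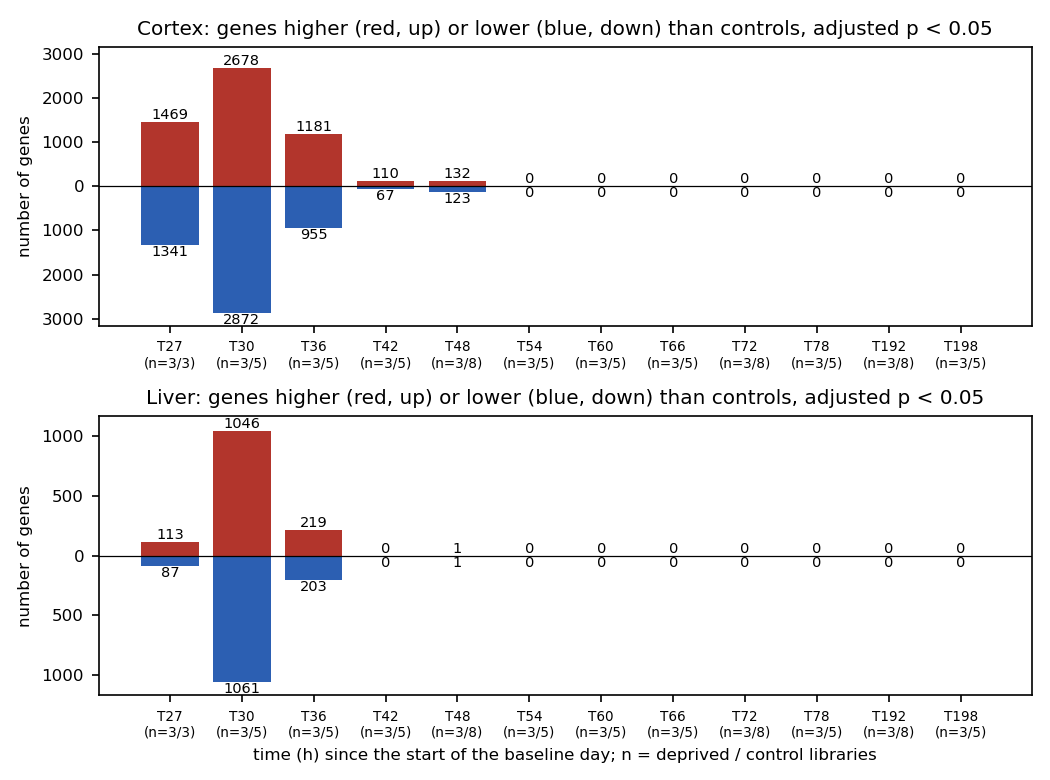
Number of genes higher (upwards) or lower (downwards) than in undisturbed mice of the same time of day at limma adjusted p under 0.05, at each sampling time in h, for cortex and liver. Counts peaked at T30, with 5550 genes in cortex and 2107 in liver, and were 0 from T54 on in both tissues.

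In the liver after 3 h of deprivation, heat shock genes rose and the lipid regulators Angptl4 and Srebf1 moved in opposite directions. Angptl4, an inhibitor of lipoprotein lipase (chromosome 17, 33773750 to 33781830), was 6.94-fold higher, at 6.94 ± 0.56 against 4.14 ± 0.19 (n = 3 each, limma adjusted p = 0.000411). Of 21 heat shock genes, 10 rose and 0 fell by limma (19 rose adjusted over the list alone, median 0.63, camera adjusted p = 2.37e-24), with Hsph1 at 1.72 (chromosome 5, 149614287 to 149636376), Hspa8 at 1.34 and Hsp90ab1 at 0.63. This call held with an estimated correlation (adjusted p = 0.00265), as did that of the same list at 6 h in liver (0.0216) and of cholesterol synthesis at T66 in cortex (0.0366), and no other call of camera did. Of 20 endoplasmic reticulum chaperones, 2 rose (17 and 1 lower adjusted over the list alone, median 0.52, camera adjusted p = 1.51e-11, and adjusted p = 0.276 with an estimated correlation), with Herpud1 at 1.22. Of 22 genes of fatty acid oxidation, 2 rose (2 adjusted over the list alone, median 0.37, camera adjusted p = 1.93e-08, and adjusted p = 0.452 with an estimated correlation). Of the 23 cholesterol genes 0 passed by limma (4 fell adjusted over the list alone, median −0.45, camera adjusted p = 2.08e-08, and adjusted p = 0.66 with an estimated correlation). Srebf1, which drives lipid synthesis genes (chromosome 11, 60199089 to 60222581), was 2.78-fold lower, with a change of −1.48 ± 0.31 (adjusted p = 0.00427). Rab36 (chromosome 10, 75037058 to 75054748) fell by 1.62 ± 0.32 on the log2 scale, and Cirbp changed by −1.13 ± 0.22 (adjusted p = 0.00157). Of the 19 core clock genes 1 rose, and of 16 immediate early genes 0 passed by limma (1 higher adjusted over the list alone).

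In all, 200 liver genes changed at 3 h (limma), 113 higher and 87 lower, 59 of them by over 2-fold. The count was 90 without T27S2, 106 without T27S3, 127 without T3N2, 100 without T3N3, 88 without T3N4 and 55 with a spread estimated from these 6 libraries alone. Of the larger rises, Ppp1r3g, a regulator of glycogen synthesis (3.71 ± 0.92, adjusted p = 0.0203), was not called without T27S2 (0.154), T3N3 (0.078) or T3N4 (0.112). Per1 (1.91 ± 0.52, adjusted p = 0.0404) was not called without T27S2 (0.205), T27S3 (0.107), T3N4 (0.33) or T3N2 (0.112), and Pck1 (1.84, adjusted p = 0.0249) was not without T27S2 (0.194), T27S3 (0.0904), T3N3 (0.0817) or T3N4 (0.196). Of the always-reported genes 4 of 25 passed, and the other 21 lay between −1.25 and 1.11.

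At 6 h the largest rise in liver was that of Ttll8 and the largest fall that of Pde6c. Ttll8, an enzyme that modifies tubulin (chromosome 15, 88890633 to 88954418), was 17.7-fold higher (1.06 ± 0.55, n = 3, against −2.80 ± 0.92, n = 5; change with the batch term 4.15 ± 0.50, limma adjusted p = 1.85e-07), and E2f8, a cell cycle repressor (chromosome 7, 48866429 to 48881596), rose by 3.45 ± 0.61. Pde6c, a phosphodiesterase known from cone photoreceptors (chromosome 19, 38132781 to 38183958), was 16.3-fold lower (−4.03 ± 0.50, adjusted p = 3.14e-07), and Dnah5, an axonemal dynein (−2.84), Cabcoco1 (−2.70), Nfe2 (−2.41), Slc2a4, a glucose transporter (−2.38), Fam83f (−2.29), Zc3h6 (−2.24) and Esrrg, a nuclear receptor (−2.19), fell. Slc25a30, a mitochondrial carrier (2.89), and Tchh (2.87) rose, as did Ces2b (3.43), Ugt2b37 (3.12), Hist2h4 (2.88) and the pseudogene Serpina4-ps1 (3.48), whose reads cannot be assigned with certainty because of close relatives. Heat shock genes rose in 17 of 21 cases (18 adjusted over the list alone, median 0.69, camera adjusted p = 2.32e-17), with Hsph1 at 2.18, Stip1 at 0.99, Ahsa1 at 0.88 and Hsp90ab1 at 0.69. Endoplasmic reticulum chaperones rose in 12 of 20 cases and fell in 1 (13 and 1 adjusted over the list alone, median 0.51, camera adjusted p = 3.67e-05, and adjusted p = 0.686 with an estimated correlation). Hyou1 rose by 1.16, and the 1 gene that fell was Trib3, a stress-induced pseudokinase (−1.83). Cirbp was 2.83-fold lower, at 3.37 ± 0.07 against 4.86 ± 0.32 (adjusted p = 7.82e-07).

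Metabolic genes of the liver moved in both directions at 6 h. Of 16 genes of bile acid synthesis and transport, 4 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.114), with the sterol transporter gene Abcg5 at −0.89, Akr1d1 at −0.67 and Cyp7b1, a sterol hydroxylase, at 1.18. Of 21 drug metabolism genes 4 fell (6 fell and 2 rose adjusted over the list alone, median −0.32, camera adjusted p = 0.0175, and adjusted p = 0.686 with an estimated correlation). Srebf1 was at −1.24, Sc5d, an enzyme of cholesterol synthesis, at −0.79, Pfkfb3, a regulator of glycolysis, at 2.35 and Fkbp5 at 1.37. Of 19 core clock genes 2 fell, among them Cry2, a clock repressor (−0.68), and 0 rose by limma (1 lower adjusted over the list alone, median −0.20). Among markers of other cells, 1 of 7 cholangiocyte genes fell in the same libraries (4 adjusted over the list alone, median −0.60, camera adjusted p = 0.0175, and adjusted p = 0.686 with an estimated correlation). Of 6 lymphocyte genes 2 fell (2 adjusted over the list alone, median −0.97), and the list did not pass (camera adjusted p = 0.0979, and adjusted p = 0.723 with an estimated correlation). In all, 2107 genes changed (limma), 1046 higher and 1061 lower, 363 of them by over 2-fold, and 4 of the 25 always-reported genes passed. The count was 792 without T30S1 and 903 with a spread estimated from the compared libraries alone (460 higher and 443 lower). The near-even balance also turned in other settings (996 and 921 without the lowest 20% of genes). Onecut1, a liver transcription factor (3.63 ± 1.05, adjusted p = 0.0139), was not called without T30S1 (0.0723) or T6N2 (0.051), and Hspa5 (0.91, adjusted p = 0.00989) not without T30S1 (0.111).

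**Figure D3:**
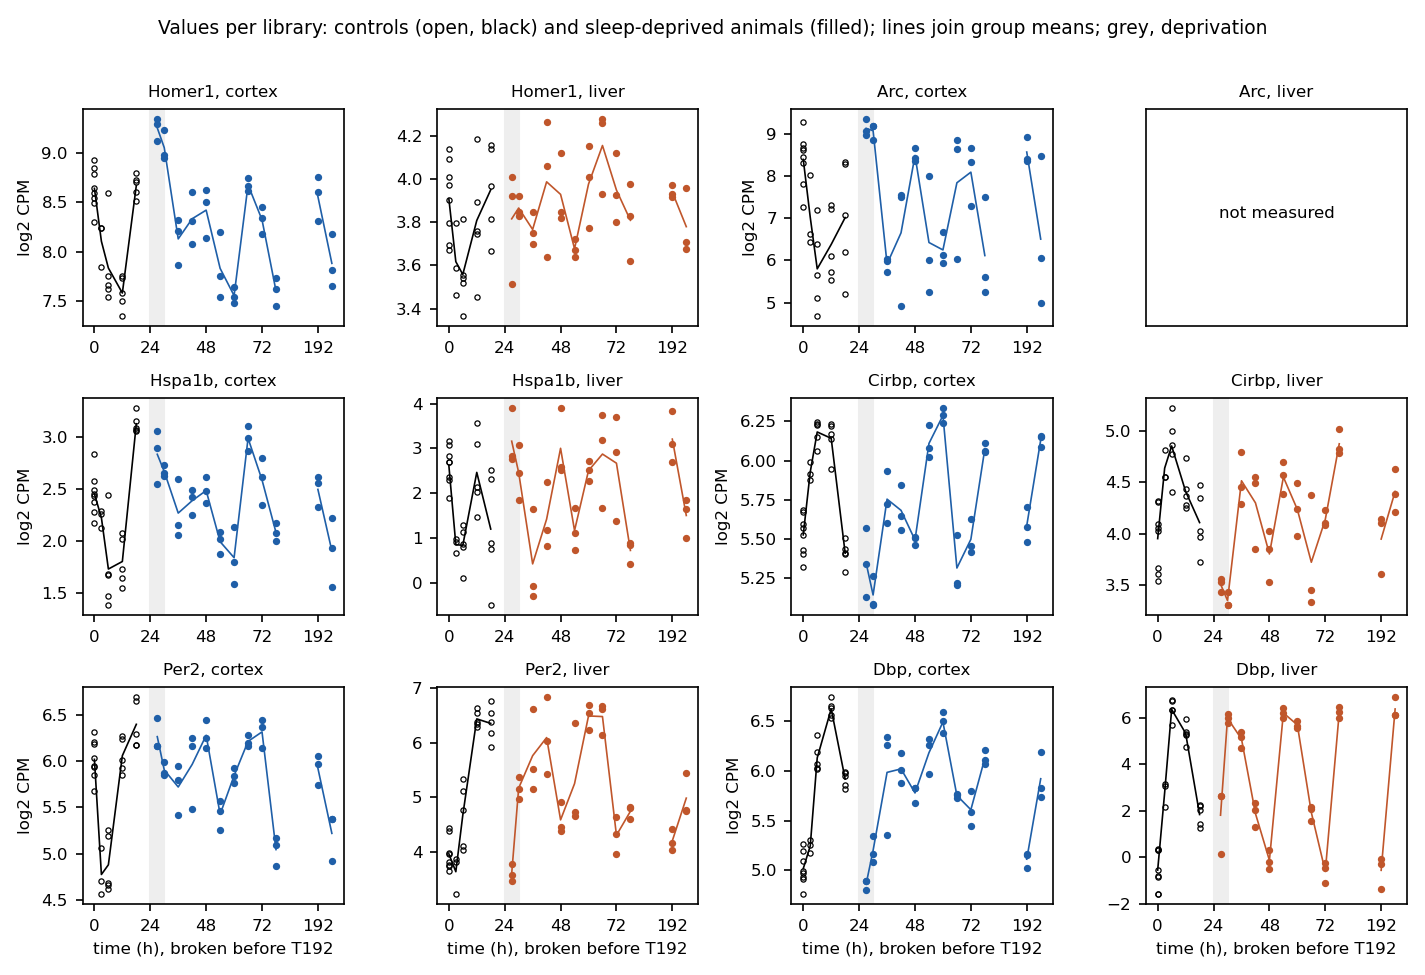
Values (log2 CPM) of Homer1, Arc, Hspa1b, Cirbp, Per2 and Dbp in every library against time in h, for undisturbed (open) and deprived mice (filled), with lines through group means and the deprivation shaded. The batch term, which was 0 in cortex, was taken out of the values. In cortex Arc lies at 9.08 ± 0.19 at the end of deprivation against 5.80 ± 1.01 in the controls, and Cirbp lies at 5.14 ± 0.11 against 6.18 ± 0.08.

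On the first recovery day the liver had lower expression of lipid synthesis genes at T36. Pklr, the liver pyruvate kinase (chromosome 3, 89136142 to 89146784), was 2.65-fold lower, at 7.86 ± 0.42 (n = 3) against 9.21 ± 0.18 (n = 5; −1.41 ± 0.23, limma F test adjusted p = 0.000964). Hcn3, an ion channel gene whose annotated span overlaps Pklr (chromosome 3, 89146074 to 89160196), was at −3.40 ± 0.55. The genes lie on opposite strands, and whether reads in the overlap were counted by strand is not given in the sources used here, so its value is uncertain. Of 15 fatty acid synthesis genes, 4 were lower and 0 higher by limma (10 lower adjusted over the list alone, median −0.82, camera adjusted p = 1.06e-08, and adjusted p = 0.705 with an estimated correlation), and Fdps, an enzyme of the cholesterol pathway, was at −1.86. Erbb4, a growth factor receptor, was at −2.16 ± 0.40. The metallothionein genes Mt2 (chromosome 8, 94172664 to 94173568; 3.09 ± 0.70, 4.11 ± 0.92 against 1.02 ± 1.35) and Mt1 (2.56) were higher, although reads of this near-identical pair cannot be assigned with certainty. Of 31 proteasome genes 2 were higher (2 adjusted over the list alone, median 0.14, camera adjusted p = 4.43e-06, and adjusted p = 0.775 with an estimated correlation). Fasn (−1.83, adjusted p = 0.019) was not called without T12N1 (0.0582), T36S2 (0.145) or T36S1 (0.0906). Srebf1 (−1.21, adjusted p = 0.0247) was not called without T12N1 (0.0684), T12N2 (0.0752), T36S2 (0.234) or T36S1 (0.117). Pnpla3, a lipase (−3.33, adjusted p = 0.0099), was not called without T36S2 (0.0532). Of the always-reported genes 4 of 25 passed on this day.

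In all, 380 liver genes changed on the first recovery day (limma F test with 2 df), 422 at T36 alone (219 higher and 203 lower) and 0 at T42 alone, where 1204 had an unadjusted p under 0.05. The day count was 219 without T36S2, 626 without T36S4 and 90 without T36S1, and with a spread estimated from the compared libraries alone 1 gene was left, Pklr. With controls of the same batch alone the day count was 182, and with the 3-level factor, a covariate found from the liver values and chosen after seeing the data, it was 202 and the T36 count 226. The T36 count was 226, 741 and 110 without T36S2, T36S4 and T36S1, and without T36S4 the balance turned, to 312 higher and 429 lower. Without a batch term 4 genes were called at T42, and after centring 2. The T42 count was 24 without T18N3, 4 without T42S4, 2 without T18N2 and 1 without T42S2 or T42S6.

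On the second recovery day 4 liver genes passed the threshold (limma F test with 4 df). Apoa4, an apolipoprotein (chromosome 9, 46240696 to 46243459), was 4.55-fold higher at T48 (2.19 ± 0.33; n = 3 and 8; adjusted p = 0.00135), and was not called without T48S4 (0.0812). Nat8f5, a member of a family of close copies, was at 1.42 ± 0.28 at T54 (adjusted p = 0.0482), and Raet1d was lower at T48 (0.0474). The count was 11 with controls of the same batch alone, 1 in a robust fit or with the 3-level factor and 0 (limma) with a spread estimated from the compared libraries alone. It was 7 without T12N1 or T12N2, 2 without T0N3 or T60S4, 0 without T48S4, and 1 without J70N1, J70N2, T0N1, T0N8, T0N9, T6N2, T6N3, T6N4, J76N2, T12N4, T12N5, T18N2, T18N3, T48S1, T54S2, T54S4, T60S2, T60S3 or T66S2. At T48 alone 2 genes were called, with 29 without T48S3, 1 without T48S1 and 0 (limma) without T48S4. At T54, T60 and T66 limma called 0, with 1144, 560 and 1230 at an unadjusted p under 0.05. The T54 count was 7 without T54S1, 3 without T6N2 and 1 without J76N1, the T60 count was 1 without T60S3 and 2 without a batch term, and the T66 count was 1 without T66S3 or T66S5. On day 3 it called 0 genes in liver, with 1045 at an unadjusted p under 0.05 and 1 called without T72S4, and on day 8 it called 0, with 377. Chance alone gives about 667 in liver, so the counts of 560 at T60 and 377 on day 8 lie below it. The T72 count was 12 without T72S4, and the T78 count was 1 without J76N1. The always-reported genes, Dbp, Cyp7a1 and Pck1 among them (25 measured), lay between −0.77 and 0.93 on day 3 and between −0.87 and 0.75 on day 8. In simulated data of the same design, again with independent noise and the change at T72 or T192 alone, fewer liver genes were found. On day 3 the shares were 47.8% of genes changed by 0.5 on the log2 scale and 76.1% of those changed by 1. On day 8 they were 43.3% and 80.6%, and they too may be too high for the real libraries.

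**Figure D4:**
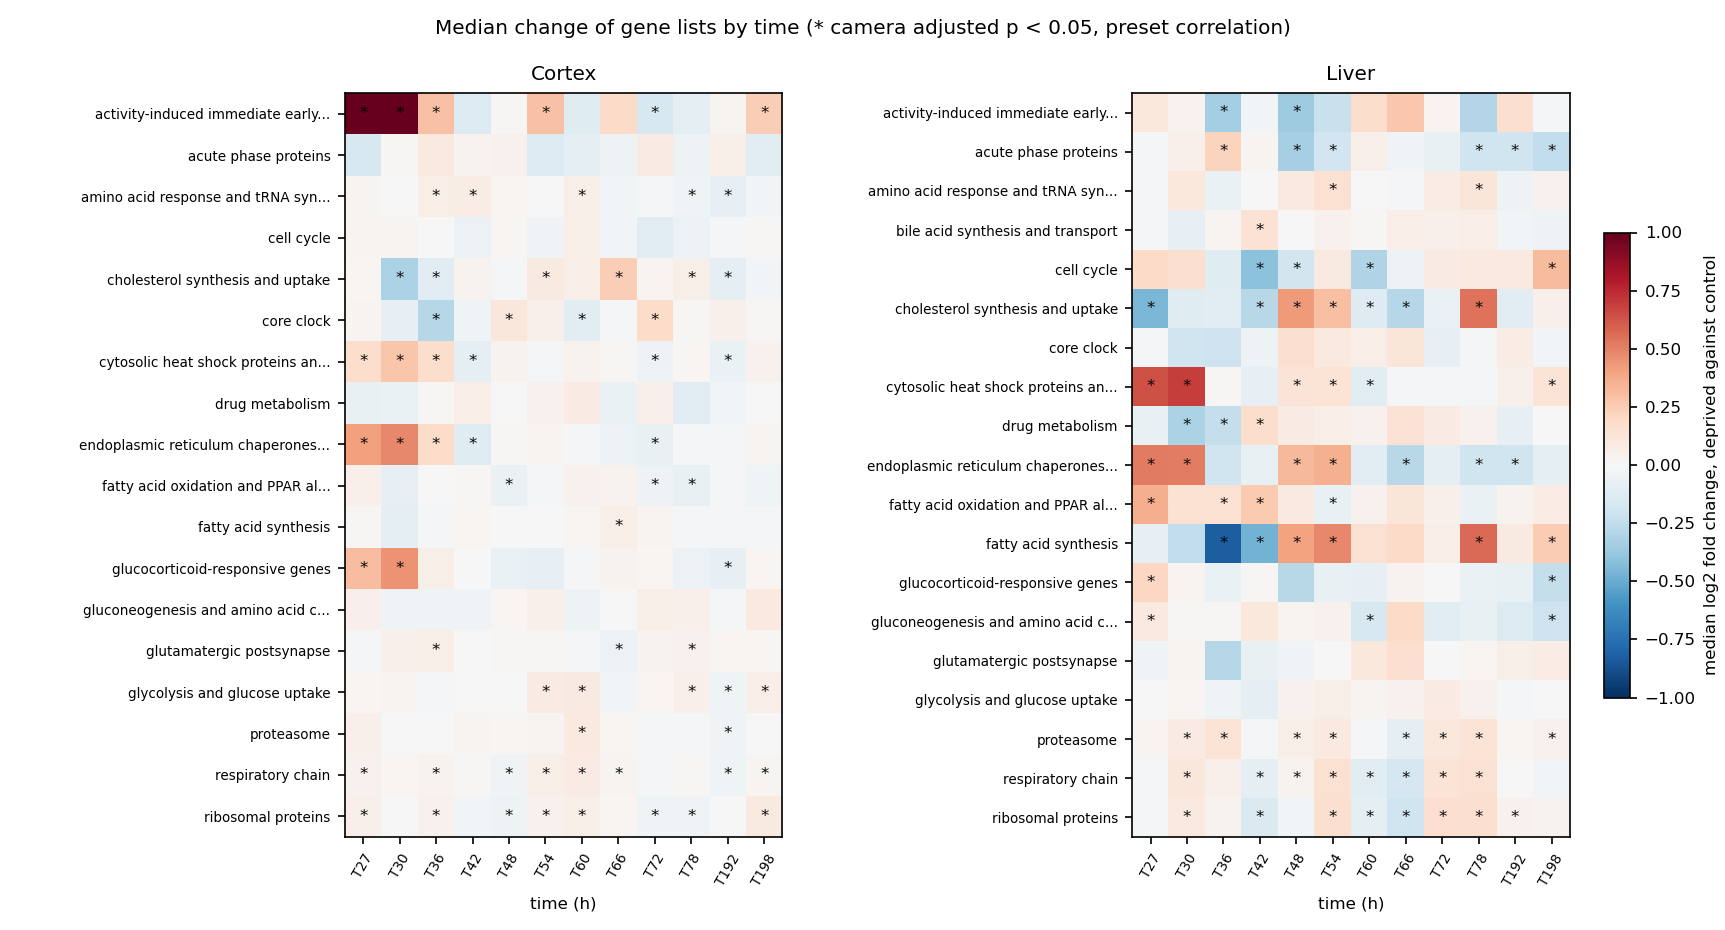
Median log2 fold change of each gene list against undisturbed mice at each sampling time in h, in cortex and liver, where an asterisk marks camera adjusted p under 0.05 with the preset correlation. In cortex at T30 the immediate early genes have a median of 1.43 and cholesterol synthesis −0.31, and in liver at T30 the heat shock genes have a median of 0.69.

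The effect of 6 h of deprivation was then compared directly between the tissues, over the 12199 genes measured in both. The effects differed for 1483 genes (limma interaction test), with 736 more positive in cortex and 747 more positive in liver. This balance turned after centring (775 and 667) and without most single libraries. Immediate early genes separated the tissues: their median change was 1.41 in cortex and 0.04 in liver over the 16 measured in both, and 11 of the 16 differed, all 11 larger in cortex (camera adjusted p = 6.23e-10, and adjusted p = 0.0599 with an estimated correlation). Junb (chromosome 8, 84974484 to 84978718) was at 1.86 in cortex and −0.67 in liver, a difference of 2.53 ± 0.60 (adjusted p = 0.00191). Heat shock genes had a larger rise in liver for 9 of 21 (medians 0.28 in cortex and 0.69 in liver, camera adjusted p = 8.37e-08, and adjusted p = 0.26 with an estimated correlation), while 2 of 20 endoplasmic reticulum chaperones differed (medians 0.48 and 0.51, camera adjusted p = 0.844). Large differences towards cortex were those of Pde6c (3.74 ± 0.61), Dnah5 (chromosome 15, 28203752 to 28472052; 3.07 ± 0.63) and Impg2, a matrix protein of the retina (2.59 ± 0.33; 1.21 in cortex and −1.37 in liver). Those towards liver were Ttll8 (−3.90 ± 0.56), Tchh (−2.91 ± 0.70), Slc25a30 (−2.91 ± 0.64), E2f8 (−2.78 ± 0.70) and Nrep (chromosome 18, 33437019 to 33464029; −2.61 ± 0.39; −0.58 in cortex and 2.03 in liver).

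Of the 12199 shared genes, 4093 changed in cortex and 1888 in liver, 789 in both and 627 in the same direction. The 315 genes higher in both compared with 163 for independent lists, the 312 lower in both with 154, and the 90 higher in cortex and lower in liver with 159. Hspb1 (1.44 in cortex and 1.81 in liver) was higher in both, and Cirbp (−1.04 and −1.50) was lower in both. Across genes, which are not independent replicates, the changes correlated with r = 0.214 and rho = 0.241. The interaction count was 806 without the liver library T30S1 (436 more positive in cortex and 370 in liver) and 826 with a spread estimated from the compared libraries alone (450 and 376).

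**Figure D5:**
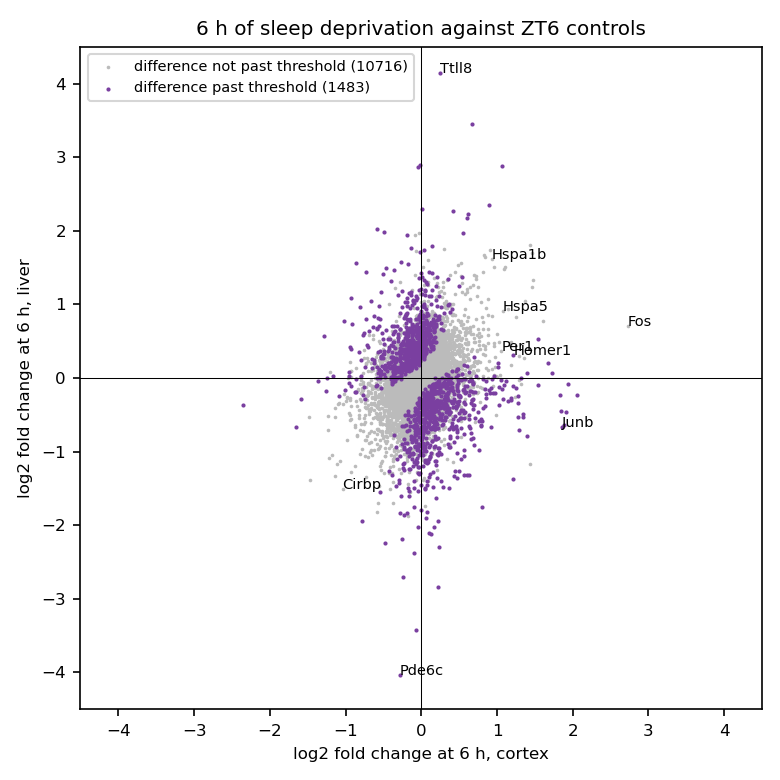
Log2 fold change after 6 h of deprivation in cortex (x axis) and liver (y axis) for the 12199 genes measured in both, with the 1483 genes whose change differed between the tissues in purple. The changes correlate with r = 0.214 across genes.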

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

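Leaving out single libraries and taking controls of the same batch alone were planned before the data were examined, but their use as tests of the choroid plexus and clock patterns was chosen only after the results were seen. The other tests of this part were chosen before.

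Choroid plexus markers were lower in cortex at 3 h of deprivation, with a median of −1.27 over 5 genes. Their mean value was −0.11, −0.10 and 0.20 in the 3 deprived libraries, and 0 of the 3 lay below all of the 23 controls of the other times (−0.48 to 1.00), which argues against fewer such transcripts in deprived mice as the source. The ZT3 controls stood at 3.04 (T3N2), 1.35 (T3N3) and 0.79 (T3N4). Without T3N2 the median was −0.997 (Ttr −2.08, Clic6 −1.50, Kl −0.19), so choroid plexus tissue in that dissection may account for part of the change, and the markers cannot decide whether it accounts for the rest.

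Core clock genes had a smaller amplitude in cortex on day 2, with a median ratio of 0.477. Without any one library it was at most 0.52, which argues against 1 library as the whole cause. The immediate early genes, which follow wakefulness, had a median ratio of 1.13 (10 of 25 smaller, and 1.26 with 6 smaller without T54S4). Noise raises this amplitude, and more so on day 2 (3 libraries per time) than in the controls (5 to 8 per time). The ratio therefore cannot decide whether wake-dependent genes swung less, and that explanation stays open. With controls of the same batch alone the ratio was 0.486, but the batch difference had been removed from the cortex values before deposit, so this cannot decide whether batch played a part, and batch stays open. The amplitude comparison itself was planned. A lasting change of the cortical clock stays open too, as a hypothesis that no other libraries tested. The tissues differed by −1.019 in the median log2 ratio (cortex minus liver).

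Heat shock genes rose and Cirbp fell in both tissues during deprivation, and 3 relations between deviations from group means were tested over the 62 mice with 100000 permutations (two-sided, adjusted over the 3). In cortex, Cirbp and the mean of the heat shock list went in opposite directions (r = −0.528, permutation p = 7e-05, adjusted p = 0.00021, rho = −0.481 with p = 0.00072 and adjusted p = 0.00216, r = −0.579 without the 2 farthest mice, −0.546 and −0.492 within the batches), as opposite control of both would give. Other gene pairs were not compared, so the relation cannot tell such control from a deviation shared by many genes of a library. The cue behind the relation was not measured and stays open. In liver the relation was weaker and stays open (r = −0.290, permutation p = 0.0225, adjusted p = 0.0337, rho = −0.291 with p = 0.0346 and adjusted p = 0.0519, r = −0.247 without the 2 farthest, −0.312 and −0.277 within the batches). Whether the tissues of a mouse share the cue cannot be told: r was 0.208 (permutation p = 0.0958, adjusted p = 0.0958, rho = 0.227 with p = 0.109 and adjusted p = 0.109, r = 0.204 without the 2 farthest, 0.202 and 0.232 within the batches).

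Of 113 groups of 4 to 10 libraries examined for the named genes, 11 had a library far from the others, where chance gives about 1 in 20 (5.65). In the cortex of the ZT6 control T6N3 these were Homer1 (8.60, others 7.54 to 7.75), Cdkn1a (4.29, others 3.55 to 3.64), Hspa1b (2.44, others 1.39 to 1.69), Npas2 (6.04, others 5.60 to 5.66) and Slco1b2 (−1.89, others −0.90 to −0.69). In other cortex controls these were Nr1d1 in J76N1 at ZT6 (7.48, others 7.29 to 7.33), Per3 in T12N4 at ZT12 (6.53, others 6.68 to 6.71) and Drd5 in T0N3 at ZT0 (−0.49, others 0.09 to 0.48). In liver controls at ZT6 they were Slc25a30 in T6N2 (2.99, others 4.46 to 4.78), Tchh in T6N4 (−3.84, others −1.65 to −0.80) and Cabcoco1 in T6N3 (0.13, others 1.17 to 1.58).

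The change at 6 h differed between cortex and liver for 1483 genes. The differences of the named genes (cortex minus liver) were 3.74 for Pde6c, 3.07 for Dnah5, 2.59 for Impg2, 2.53 for Junb, −3.90 for Ttll8, −2.91 for Tchh, −2.91 for Slc25a30, −2.78 for E2f8 and −2.61 for Nrep. That of Ppp1r3g (2.56 ± 0.86, limma adjusted p = 0.0369) was not called without the cortex libraries T6N3 (0.0502), T6N4 (0.0513), T30S1 (0.0705), T30S3 (0.0549) or T30S4 (0.075), nor without the liver libraries T30S1 (0.138), T30S3 (0.143), T6N2 (0.0686), J76N2 (0.052) or T6N4 (0.0559).

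Among the entries without a gene name, which no comparison used, 29 of 77 changed at 6 h in cortex (5 higher and 24 lower, the largest by −1.18) and 6 of 35 in liver (2 higher and 4 lower, the largest by −2.06). Of all named genes, 32.4% changed at 6 h in cortex and 15.8% in liver. The counts of unnamed entries were not tested against these shares.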

How the results depend on the processing

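The 3-level factor of the liver and the gene set tests under the settings of the fits, other than the estimated correlation, were chosen only after the results were seen. No named gene whose change was called changed sign under any alternative that was run. Much of this was fixed beforehand. Genes named for the size of a change after deprivation had been picked with every deprived library on 1 side of the controls. A robust fit, leaving out low genes and, in cortex, leaving out the batch term do not alter the changes. Baseline ranges and rhythm changes have no sign. The balance of higher and lower calls, near even in these cases, did turn after centring in cortex at 3 h (1469 and 1341 to 1324 and 1470) and at T48 (132 and 123 to 105 and 143, and to 57 and 64 without T48S3). Without the lowest 20% of genes it turned at 6 h in cortex (2678 and 2872 to 2553 and 2503) and in liver (1046 and 1061 to 996 and 921). In liver at 6 h it turned as well without a batch term, with the compared libraries or same-batch controls alone and without T30S3, J76N1 or T6N2. At T36 in liver it turned without T36S4 (219 and 203 to 312 and 429). For the tissue difference it turned after centring, with the compared libraries alone, with the 3-level factor and without most single libraries (736 and 747 to 436 and 370 without the liver library T30S1). The counts of cortex at 3 h, 6 h and on day 1, and both median clock ratios, stayed within 1.5 times under every alternative other than leaving out libraries. Without a batch term the count was 321 on day 2, 5 on day 3 and 189 for the rhythm in cortex, and 1 for the rhythm in liver. With the spread taken from the compared libraries alone it was 76 on day 2 and 2 on day 3 in cortex, 55 at 3 h, 903 at 6 h, 1 on day 1 and 0 (limma) on day 2 in liver, 826 for the tissue difference and 12 gene lists for liver T36. Controls of the same batch alone gave 27 on day 2 and 0 (limma) for the rhythm in cortex, and 182 on day 1 and 11 on day 2 in liver. Batch 1 controls alone gave a baseline count of 4672 in cortex and 4346 in liver, from fewer libraries. A robust fit gave 1 on day 2 and 1 for the rhythm in liver. The 3-level factor gave 202 on day 1 and 1 on day 2 in liver. Camera with an estimated correlation called 0, 0 and 0 lists in cortex at T27, T30 and T36 and 1, 1 and 0 in liver, against 8, 5, 11, 6, 8 and 6 with the preset correlation. Without the lowest 20% of genes it called 5 in cortex at T27 and 5 in liver at T30. In cortex the batch difference was 0 for every gene, so leaving out the batch term moved the standard errors and not the changes. The clock ratio there was 0.477 either way. For the other shifts, except where libraries were fewer, the cause was not tested. Pairs of libraries with the same trailing number of the animal code correlated over 0.1 in 32 of 331 cases in cortex and 71 of 331 in liver. The median for each number lay between −0.012 and 0.012 in cortex and between −0.052 and 0.086 in liver. Pairs with different numbers were not examined, so these values cannot decide whether the number pairs mice. As a block the number gave 65 on day 2 and 7 for the rhythm in cortex, and 145 on day 1 and 1 on day 2 in liver, and it moved no other count of a comparison by over 1.5 times. At single times the block gave 105 at T42 and 2 at T54 in cortex and 206 at T36 and 2 at T42 in liver, no batch term gave 419 at T48, 2 at T54, 14 at T66 and 6 at T72 in cortex and 4 at T42 and 2 at T60 in liver, centring gave 2 at T42 in liver, and the 3-level factor gave 226 at T36.

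Leaving out 1 library at a time, counts ran in cortex from 1874 to 2309 at 3 h, 4118 to 5655 at 6 h, 1176 to 2011 on day 1, 68 to 947 on day 2, 0 to 1 on day 3, 0 to 20 on day 8, 6449 to 7303 at baseline and 0 to 1172 for the rhythm (limma). In liver they ran from 88 to 186, 792 to 2136, 90 to 626, 0 to 7, 0 to 1, 0 to 0, 6449 to 6972 and 0 to 1 in the same order, and for the tissue difference from 806 to 1915. The cortex clock ratio ran from 0.455 to 0.52. Of 433 results on named genes, 147 lost their call without some library, 89 with the compared libraries alone, 39 with the number block, 36 of 272 with same-batch controls, 27 of 158 with the 3-level factor, 21 with a robust fit, 7 without batch, 5 after centring and 0 of 358 without low genes (limma). Of the 61 baseline results, 4 lost it with a cosine fit and 2 with batch 1 controls. Results on genes in the lowest 20% could not be retested without low genes, which is why 358 of the 433 remained there. The change of pseudocount was not run, since the values were logarithms already. Unknown depth limits the low genes, for which counting error cannot be told from spread between mice.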

Other observations

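The counts over other splits of the libraries were planned before the data were examined, and no test of this part was chosen after results were seen. The gene groups described here were picked after their values were seen.

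Some gene groups had called members or a camera call at recovery times at which no single gene passed over all genes. They were picked from all lists and times, while each p-value was adjusted within 1 list or within 1 time of 1 tissue. Only cholesterol synthesis at T66 in cortex was also called with an estimated correlation. At T66 in cortex, cholesterol synthesis genes were higher than in ZT18 controls, with 15 of 23 called adjusted over the list alone (limma, 0 over all genes, where 1627 had an unadjusted p under 0.05). Their median was 0.25 (camera adjusted p = 3.42e-19, and adjusted p = 0.0366 with an estimated correlation), and they included the enzyme genes Sqle, Msmo1, Fdft1 and Hmgcs1. At T60, 10 of 31 proteasome genes were higher adjusted over the list alone (median 0.10, camera adjusted p = 1.56e-18, and adjusted p = 0.0815 with an estimated correlation). At T72, 8 of 20 core clock genes were higher and 2 lower adjusted over the list alone (median 0.18, camera adjusted p = 3.68e-06, and adjusted p = 0.123 with an estimated correlation), among them Dbp (0.59) and Nr1d1 (0.50). In the same libraries 6 of 12 oligodendrocyte markers were lower adjusted over the list alone (median −0.26, camera adjusted p = 1.11e-10, and adjusted p = 0.319 with an estimated correlation). The T48 libraries had these markers higher than the same ZT0 controls, so the direction was not the same at both times.

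In liver at T42, markers of pericentral hepatocytes, the cells around the central vein, were higher in 7 of 12 cases adjusted over the list alone (median 0.40, camera adjusted p = 2.62e-06, and adjusted p = 0.109 with an estimated correlation), as were 7 of 22 genes of fatty acid oxidation (median 0.26, camera adjusted p = 5.44e-08, and adjusted p = 0.293 with an estimated correlation) and 5 of 16 bile acid genes (median 0.14, camera adjusted p = 0.000764, and adjusted p = 0.109 with an estimated correlation). At T78, 7 of 23 cholesterol synthesis genes (median 0.54, camera adjusted p = 5.69e-12) and 7 of 15 fatty acid synthesis genes (median 0.57, camera adjusted p = 6.69e-07) were higher adjusted over the list alone, each with adjusted p = 0.479 with an estimated correlation. Markers of Kupffer cells, the macrophages of the liver, had a median of −0.83 there, with 0 called by limma over the list alone (camera adjusted p = 3.38e-08, and adjusted p = 0.479 with an estimated correlation).

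Counts of called genes were compared with those of other splits of the same libraries. The real split called the most genes in cortex at 6 h (5550 genes, at most 3498 in the other splits, 1 of 56 splits as large) and at baseline (7162 and 1214, 1 of 100). It also did in liver at 6 h (2107 and 400, 1 of 56) and at baseline (6937 and 1670, 1 of 100), and for the tissue difference (1483 and 370, 1 of 56). Chance is an unlikely source of these counts, but such splits cannot set aside a difference in how groups were handled. On cortex day 1 only 1 of 100 splits was as large (1983 genes and at most 1494 in the others), but the real count was 1176 without T36S1, below that of another split. On liver day 2 only 1 of 100 splits was as large, but with 4 genes against 3 in the next, and the real count was 0 (limma) without T48S4 and 1 without T48S1, T54S2 and other single libraries. On liver day 1, 3 of 100 splits were as large as the real count of 380, which fell to 90 without T36S1 and 219 without T36S2 and was 626 without T36S4. Another split called 1924, several times the real count, which points to a structure of the samples, so that count does not stand clear of other splits. In cortex on day 2 chance could not be excluded (132 genes, 5 of 100 as large), nor for the rhythm (2 genes, 11 of 100), and other splits called up to 1693 and 1302, which again points to a structure of the samples. T54S4, without which 947 genes were called on day 2 and 1172 for the rhythm, had an Arc value of 8.02 against 5.25 and 6.02 in the other T54 libraries. At 3 h the splits are too few for such a share, with 2810 genes and at most 0 in the others in cortex (1 of 10), and 200 and at most 1 in liver (1 of 10). For the counts of 0 by limma on day 3, day 8 and for the liver rhythm all 100 splits were as large, with at most 2 and 11 genes in cortex on days 3 and 8, 1 and 1 in liver, and 3 for the liver rhythm.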
